A study of Mus musculus with 6 samples.

How the data were processed

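The values used are the count matrices that the authors deposited, 1 per library, holding raw UMI counts for 32285 genes in 68724 barcodes already called as cells upstream. The submitters' processing notes name Cell Ranger 1.0.0 and the mm10 genome, whereas per the file headers the counts were written by Cell Ranger 6.1.2, and the release of the gene annotation used upstream is not given in the sources used here. Reads were not used here, and nothing upstream of the counts was repeated. Gene IDs and coordinates were taken from GENCODE vM21 on GRCm38, where 571 of 571 genes looked up were found. The design, the gene lists, the rule for naming genes and 15 alternatives were written down before the data were examined.

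Cells were kept with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs. This left 11758 and 12397 barcodes on day 0 (ZT4 and ZT16), 10984 and 11233 on day 1, and 9488 and 8172 on day 3, with 10.8% and 11.7% of day 0 barcodes, 2.1% and 2.1% of day 1 and 4.3% and 4.9% of day 3 over the mitochondrial limit. Doublet scores came from scrublet in each library. Its automatic threshold marked 3 of 9488 barcodes in the day 3 ZT4 library (0.03%), which means it did not work there, so the barcodes with the highest scores were left out at 0.8% per 1000 barcodes of the library, as fixed in the design. This removed 1106 and 1229 barcodes on day 0, 965 and 1009 on day 1, and 720 and 534 on day 3, and kept 10652 and 11168, 10019 and 10224, and 8768 and 7638 cells.

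Counts were scaled per cell and log transformed for clustering only, with 2000 variable genes, 30 principal components, 15 neighbours, Jaccard weights and Leiden clustering at resolution 1.0 on all 6 libraries together, without batch correction. This gave 39 clusters. A pair of clusters of at least 100 cells had too few detected markers of their best-matching class to be named. These were divided once more at resolution 0.5 into parts, a step chosen after the clusters were seen, which made 50 clusters. A cluster took the name of a class, written with the ending -like, when at least 3 of that class's fixed markers were detected. Detected means at least 2-fold over other cells and in at least 10% of its cells. Its 10 leading genes also had to hold no more markers of another class. A cluster with median UMIs under 1/3 of the library's and no class marker among those genes stayed unnamed. This left out cluster 17, with 11 detected mature muscle markers and 318 and 508 cells on day 1 (ZT4 and ZT16). It also left out clusters 100 and 101 (753 and 455 cells), with 12 endothelial markers each. Of the 50 clusters, 38 were named as 1 of 15 classes and 12 stayed unnamed, among them clusters of far lower depth than the rest and the Lyve1-led cluster, which holds macrophage genes and a lymphatic marker and is counted with the immune cells where these serve as denominator. Erythroid-like, B cell-like, T cell-like and mast-like classes are small or sit in mixed clusters, and the doublet step removed most barcodes with mast cell genes on day 0, so their genes are not reported singly here. Where large enough to compare, these classes do enter the counts of classes. The name mast-like is doubtful. On day 3 at ZT4 that class held 79 cells, while 0 barcodes with at least 5 UMIs of mast cell genes were left after doublet removal. The threshold of 5 UMIs for counting mast cell barcodes was chosen after looking, with 20 also tried.

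Within a class, UMIs were summed over the cells of a library and divided by the sum of the class to give CPM. Fold differences add 0.5 UMI to each count, and their intervals are exact conditional binomial intervals for the ratio of 2 Poisson counts at 95%. Shares have exact binomial intervals. A class was compared where both libraries had at least 50 cells, so myogenic-like and fibro-adipogenic-like cells of day 1 were not compared. With 1 library per group no test was run, no p-value is given and no changed genes are counted. A gene with 0 UMIs in a group is given as a lower bound against a floor of 3 UMIs. Cell cycle phases were not called. The median log2 value over all genes was beyond 0.1 in endothelial-like cells of day 0, at -0.112, and in B cell-like cells of day 1, at 0.171, and no correction was made for it.

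The 24 gene lists were clock activators, Per and Cry repressors, clock nuclear receptors and output factors, chemokines and cytokines, NF-kB targets, glycolysis, NAD synthesis and shuttles, oxidative phosphorylation, quiescence, activation and differentiation, S phase, G2M, immediate early and dissociation genes, heat shock, cold-inducible RNA-binding genes, glucocorticoid response, type I interferon response, matrix, inflammatory macrophage, resident and repair macrophage, neutrophil trafficking and maturation, ribosomal proteins, sex-linked genes and genes of other cell types. A list is given as the median log2 value of its members with at least 30 UMIs in both groups together, and as a percentile among 10000 random lists drawn from 20 bins of like expression. A median from thinned cells can rest on fewer members, since those under the limit of 30 UMIs drop out. Limits of a list median come from 500 Poisson draws. Lists and genes are reported for 6 classes, a restriction chosen after the values were seen. The quiescence list and the activation and differentiation list hold myogenic genes, whichever class they are given for.

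Besides list members, genes were named by a rule fixed in advance. In myogenic-like cells the 10 genes higher and 10 lower with the largest fold at the interval bound nearest 1 were named on each day, and 5 and 5 in other classes. Over the days, 8 and 8 genes with the largest smallest fold in the same direction were named, and after injury 12 and 12 by the smaller of the ZT4 and ZT16 folds. The rule over the days was written for 3 days, but could be applied to day 0 and day 3 only. Ranked genes had at least 100 UMIs and at least 50 CPM in the higher group. Mitochondrial, ribosomal protein, haemoglobin, sex-linked, immunoglobulin and unnamed predicted genes were left out, as were genes under 10% of another compared class's CPM in the same library. A fold of 1.5 was called a size difference. Some genes that the rule names are not reported here.

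Other settings tried, fixed in advance, were no cell filter, a stricter filter (500 genes, 1000 UMIs, 5% mitochondrial), doublets kept, Leiden resolutions of 0.5 and 2.0, each library clustered alone, immune or non-immune cells as denominator, median-of-ratios size factors, totals without mitochondrial and ribosomal protein genes, mean per-cell CPM, cells thinned to 1000 UMIs, free RNA subtracted, clusters weighted alike, and list members with at least 100 UMIs or at least 1 UMI. The free RNA share of a class was estimated from neutrophil and haemoglobin UMIs, and in myogenic-like cells it was 1.32% and 4.70% on day 0 and 2.17% and 6.81% on day 3 at ZT4 and ZT16. Added after seeing the data were clusters not divided further, myogenic-like cells without cycling cells, no free RNA subtraction where the estimated share is over 20%, values of small day 1 groups, and cycling cells thinned to 3000 UMIs. A direction counts as turned only for list medians of at least 1.2-fold and genes of at least 1.5-fold with an interval that leaves out 0, limits set after a first look at the alternatives.

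The method was run on simulated counts made from the myogenic-like cells, with 50 genes changed at each of 1.5-, 2-, 4- and 8-fold. In the day 0 comparison (8378 genes) the interval held the true value for 95.5% of unchanged genes and lay on the right side of 0 for 98%, 100%, 100% and 100% of changed genes at those folds. In the day 3 comparison (10501 genes) it held it for 95.1%, with 96%, 100%, 100% and 100% on the right side. A list of 15 raised genes reached percentile 100 in both, and an unchanged list stayed at percentile 15.2 and 11.9. Simulated counts hold no animal or library differences and no clustering of UMIs in single cells. They were drawn from the Poisson model that the intervals assume, so coverage near the set level was fixed in advance. This checks counting error alone. Work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 (with its scrublet), anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.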

Results

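Single-cell RNA profiles were collected from the tibialis anterior, a muscle of the shin, of wild-type mice on day 0 (uninjured), day 1 and day 3 after injury with cardiotoxin. This snake venom toxin destroys muscle fibres and sets off regeneration from muscle stem cells. Living mononucleated cells were sorted by exclusion of propidium iodide, and on each day 1 library was made at zeitgeber time 4 (ZT4) and 1 at ZT16, hours counted from lights on. On day 0 the ZT4 and ZT16 libraries held 13361 and 14079 barcodes with 76575993 and 82114677 UMIs (transcript molecules). On day 1 they held 11235 and 11493 barcodes with 72747703 and 96690582 UMIs, and on day 3 they held 9930 and 8626 barcodes with 132221721 and 109537133 UMIs. Filtering and doublet removal left 58469 cells, with a median UMI count per cell at ZT4 and ZT16 of 5003.5 and 4831 on day 0, 3173 and 4600 on day 1, and 11064.5 and 11125 on day 3. Every group is 1 library, so no difference below has a replicate check. Differences between animals, muscles and libraries stay mixed with day and collection time. On day 1 and day 3 the hour of injury may also have gone with collection time, and such effects could not then be told apart. Intervals in brackets are exact 95% limits that cover counting error only. Levels are UMI counts scaled to the class total (CPM), and log2 values are ZT16 over ZT4 unless said otherwise.

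The first question was which cells make up the muscle on each day and whether collection time goes with their shares. Uninjured muscle held mainly fibro-adipogenic-like cells, the Pdgfra-bearing stromal cells that lay down matrix (29.2% of kept cells at ZT4 and 22.7% at ZT16), and endothelial-like cells (20.4% and 23.0%). It also held droplets with mature muscle transcripts (13.5% and 18.2%) and myogenic-like cells, which hold the Pax7-bearing stem cells (8.35% and 9.29%). On day 1 neutrophil-like cells, the first immune cells to enter damaged muscle, made up 48.1% at ZT4 and 41.3% at ZT16. Monocyte-macrophage-like cells, which clear debris, made up 38.8% and 40.3%. Myogenic-like cells then numbered 14 at ZT4 and 35 at ZT16. On day 3 monocyte-macrophage-like cells held 58.1% and 62.6%, and antigen-presenting dendritic-like cells 13.4% and 11.3%. Myogenic-like cells held 7.95% [7.39, 8.54] and 6.44% [5.90, 7.02], and neutrophil-like cells 3.24% and 2.27%. Unnamed clusters held 16.1% and 14.3% of cells on day 0, 3.69% and 6.09% on day 1, and 3.70% and 4.06% on day 3. Shares count cells that came through dissociation and sorting, and the mature-muscle-like droplets may hold fibre fragments or free RNA.

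Between collection times the myogenic-like share was slightly higher at ZT16 on day 0 (889 and 1038 cells, log2 0.16 [0.03, 0.29]). It was lower at ZT16 on day 3 (697 and 492 cells, log2 -0.30 [-0.47, -0.14], and -0.13 when divided by non-immune cells only). Neutrophil-like cells were fewer at ZT16 on day 1 (log2 -0.22 [-0.28, -0.16], -0.13 among immune cells and -0.12 with each library clustered alone). On day 3 they were fewer again (log2 -0.52 [-0.80, -0.24], but 0.06 with each library clustered alone). Monocyte-macrophage-like shares differed little, at log2 0.06 on day 1 and 0.11 on day 3. Endothelial-like cells, which line vessels, were 1.95-fold higher at ZT16 on day 1 (2.66% and 5.17%, log2 0.96 [0.75, 1.18]), but the value was 0.12 among non-immune cells. Mural-like cells, the pericytes and smooth muscle cells around vessels, were higher at ZT16 on day 0 (log2 0.39) and on day 1 (log2 0.76, -0.09 among non-immune cells). Fibro-adipogenic-like cells were lower at ZT16 on day 0 (log2 -0.37 [-0.44, -0.29]). So was a cluster led by Lyve1, Cd163 and Timd4, genes of resident macrophages (9.28% and 5.85%, log2 -0.67, 0.05 among immune cells). Dendritic-like cells were lower at ZT16 on day 0 (log2 -0.37, but 0.35 among immune cells and 0.88 with each library clustered alone). On day 3 they were lower at ZT16 as well (log2 -0.25). Tenocyte-like cells, which build tendon, were higher at ZT16 on day 0 (log2 0.41, with the difference gone at -0.004 when doublets were kept).

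**Figure D1:**
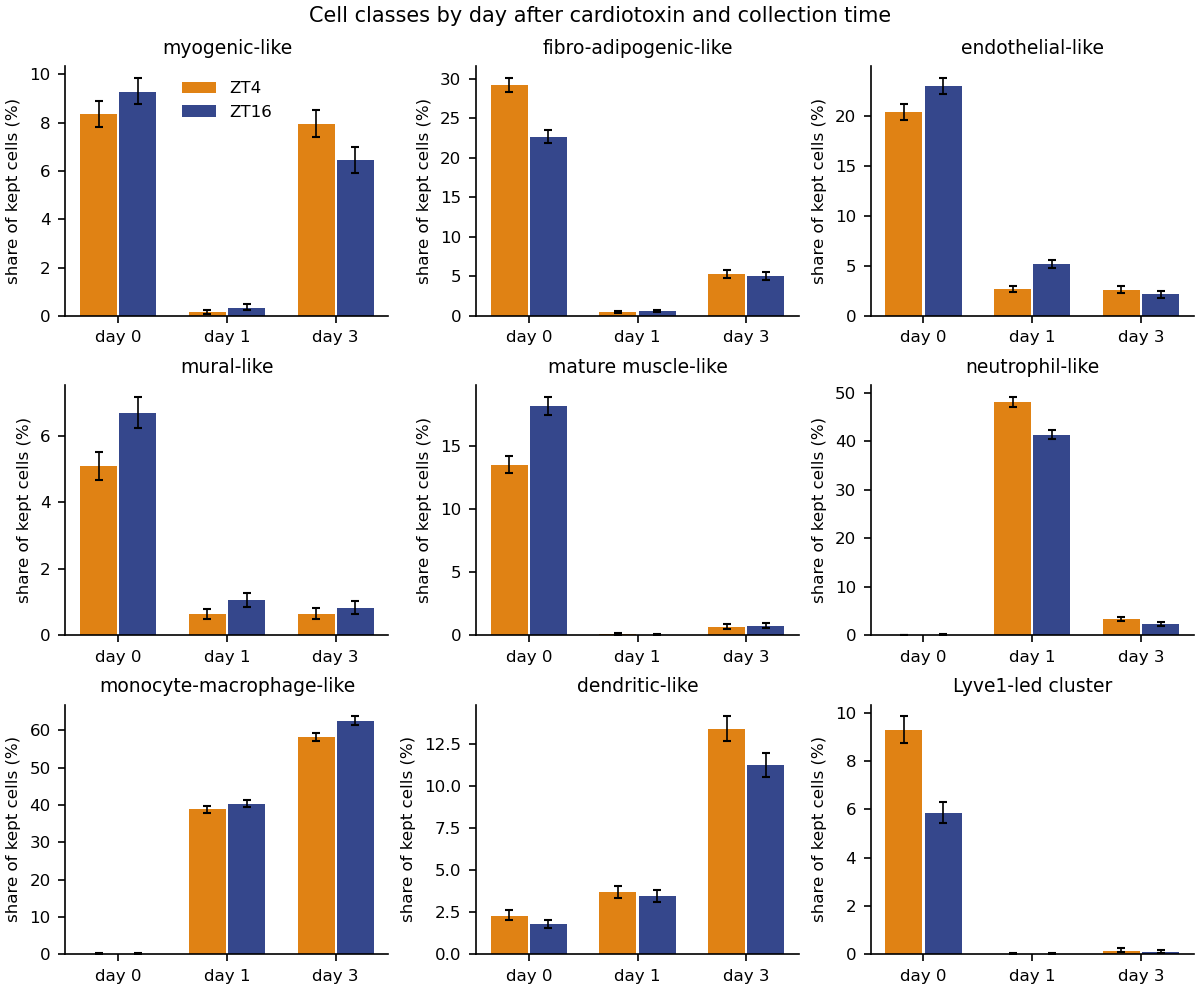
Share of kept cells in each class by day after cardiotoxin and collection time. Error bars are exact 95% binomial intervals.

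The second question was whether muscle stem cells of uninjured muscle differ between ZT4 and ZT16 in their clock genes and in clock-linked genes. Myogenic-like cells of day 0 (889 cells with 5201006 UMIs and 1038 with 7764175 UMIs) carried a clear clock difference. The gene of the repressor REV-ERB alpha, Nr1d1 (ENSMUSG00000020889, chromosome 11:98767932-98775333, minus strand), was lower at ZT16, at 117 and 28.7 CPM (log2 -2.03 [-2.26, -1.81]). The activators that the clock builds on were lower as well, with Npas2 (ENSMUSG00000026077, 1:39193731-39363236, plus strand) at log2 -1.66 [-2.38, -1.01]. Arntl, which codes for BMAL1 (ENSMUSG00000055116, 7:113207465-113314126, plus strand), was at -1.06 [-1.72, -0.43], while Clock did not differ (-0.09). Period and cryptochrome genes, whose products shut the activators off, were higher at ZT16. Per2 (ENSMUSG00000055866, 1:91415982-91459324, minus strand) was at 4.42 and 27.2 CPM (log2 2.59 [1.995, 3.308]). Cry1 (ENSMUSG00000020038, 10:85131700-85185064, minus strand) was at 3.85 and 15.5 CPM (log2 1.98 [1.32, 2.77]) and Per3 at 31.9 and 69.8 CPM (log2 1.13). Per1 (-0.15) and Cry2 (0.16) did not reach 1.5-fold. Among clock output genes, Bhlhe41 (log2 1.13), Tef (0.91), Usp2 (0.79), Hlf (0.67) and Nfil3 (0.59) were higher at ZT16 and Dbp was not (193 and 172 CPM, log2 -0.16). As lists, the activators had a median of -1.06 (3 genes, percentile 0.04 among 10000 random lists of like expression). The Per and Cry repressors had 1.13 (5 genes, percentile 100). They had 0.48 in cells thinned to 1000 UMIs, where fewer members may pass the limit of 30 UMIs. The output factors had 0.59 (11 genes, percentile 100). Coordinates are 1-based on GRCm38 (mm10) with GENCODE vM21 gene IDs.

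Glucocorticoid-responsive genes also differed by collection time in these cells. Tsc22d3, which codes for the anti-inflammatory protein GILZ (ENSMUSG00000031431, X:140539528-140600659, minus strand), was at 55.0 CPM at ZT4 and 269 CPM at ZT16 (log2 2.29 [2.11, 2.47]). Fkbp5, which codes for a chaperone partner of the glucocorticoid receptor (ENSMUSG00000024222, 17:28399094-28517527, minus strand), stood at 9.04 and 34.9 CPM (log2 1.94). Zbtb16 (1.58), Arrdc2 (1.45), Ddit4 (0.72) and Klf9 (0.69) were higher too. Angptl4, a gene that fasting and fatty acids switch on, was lower at 26.5 and 1.67 CPM (log2 -3.94 [-4.93, -3.17]). The list of 15 genes had a median of 0.45 (percentile 100), with 6 genes at least 1.5-fold higher and 1 lower. The cold-inducible RNA-binding gene Cirbp was lower at ZT16 (194 and 88.2 CPM, log2 -1.13) and its relative Rbm3 did not differ (-0.02), giving a list median of -0.58. In glucose handling, Hk2, which codes for a hexokinase, was higher (log2 1.79), Slc2a1, a glucose transporter gene, was higher (0.76) and Pfkfb3 was lower (-1.09). The glycolysis list, however, had a median of -0.02 (percentile 43.0), while the list of NAD synthesis, use and shuttles had 0.13 (percentile 93.2). Oxidative phosphorylation was at 0.05 (percentile 90.4), but at -0.03 (percentile 49.7) without the dividing cells described below.

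**Figure D2:**
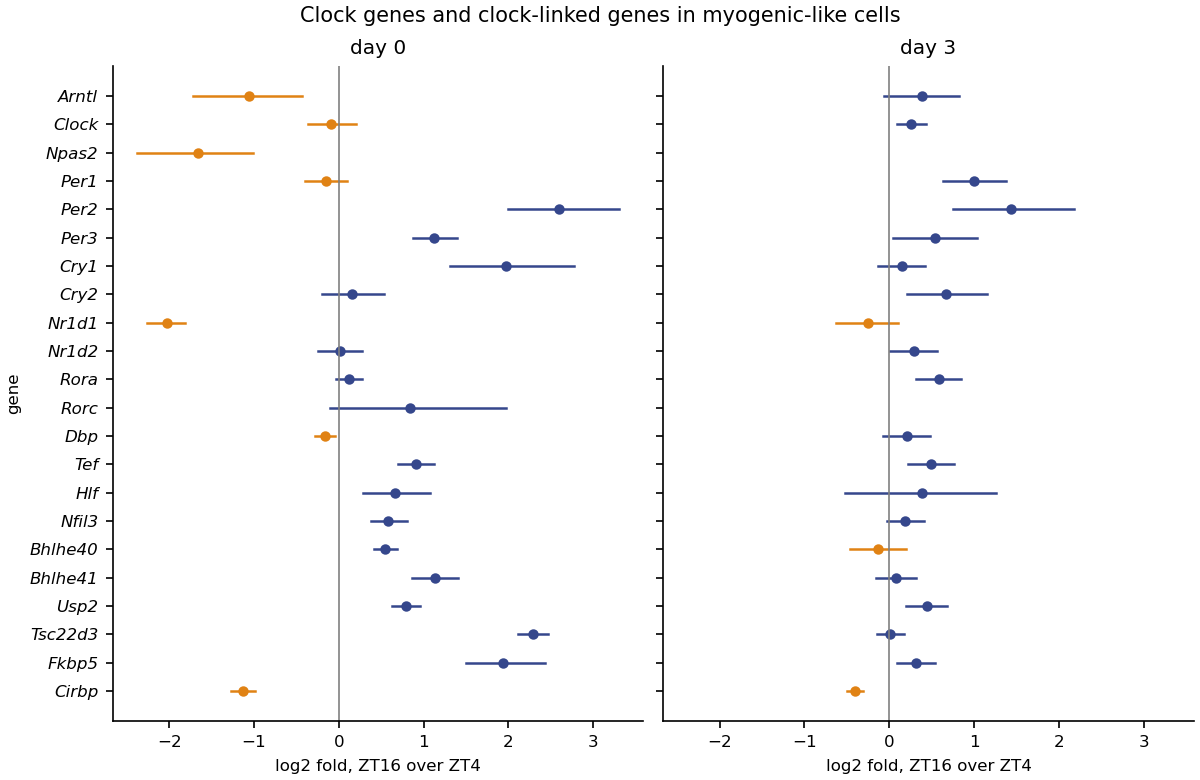
Log2 fold between ZT16 and ZT4 of clock genes and clock-linked genes in myogenic-like cells of day 0 and day 3. Bars are exact 95% counting intervals.

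The largest difference between the day 0 myogenic-like groups was in genes of dividing cells, which resting stem cells lack. All 20 measured S phase genes (median log2 2.19) and all 20 measured G2M genes (median log2 4.52, 4.39 with genes near 0 at their bound) were at least 1.5-fold higher at ZT16, both at percentile 100. Mki67, a proliferation marker gene (ENSMUSG00000031004, 7:135689784-135716361, minus strand), stood at 1.35 and 56.4 CPM (log2 5.29 [4.33, 6.71]). Top2a, which codes for the topoisomerase that untangles replicated DNA (ENSMUSG00000020914, 11:98992943-99024189, minus strand), was at 1.54 and 93.6 CPM (log2 5.84 [4.94, 7.15]). Cdk1, the kinase gene of mitotic entry, was at 3.08 and 59.9 CPM (log2 4.24). The rule for naming genes put Prc1, a spindle midzone gene with 2 and 444 UMIs (149-fold [40.9, 1232]), Pclaf, Birc5 and Stmn1 (15.2 and 310 CPM) beside them. It also named Hist1h2ap, Hist1h1b and Hist1h2ae, whose near-identical gene copies make single-gene counts uncertain. Ube2c, which marks mitotic proteins for destruction, had 0 UMIs at ZT4 and 378 at ZT16, at least 84.4-fold higher. Aurkb was at least 36.8-fold higher and Plk1 at least 6.70-fold higher. Most of the difference sits in a small number of cells. A cell was counted as cycling with at least 3 UMIs of the G2M genes other than Hmgb2, a limit chosen after the values were seen. By this, 6 of 889 cells at ZT4 (0.675% [0.248, 1.46]) and 60 of 1038 at ZT16 (5.78% [4.44, 7.38]) were cycling. With every cell thinned to 3000 UMIs the shares were 3 of 863 (0.348%, 26 shallower cells left out) and 48 of 1008 (4.76%, 30 left out). Mural-like cells, which should lack the program, had 0 of 543 and 1 of 747 such cells at median depths of 3509 and 3853 UMIs against 5589 and 6759.5 in myogenic-like cells. After thinning they had 0 of 351 (upper limit 0.855%) and 0 of 513 (upper limit 0.585%), with 192 and 234 left out. Without the cycling cells the G2M median was 0.24 (3 genes still measured), a fall that follows from picking the cells by these genes. The S phase median was then 0.34 (14 genes, percentile 99.8), while the clock values stayed (Per2 2.69, Nr1d1 -1.89, repressor list 1.24).

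Lower at ZT16 by the naming rule were Nr1d1, Bcl6, which codes for a transcriptional repressor (58.6 and 17.6 CPM, log2 -1.73), and Igfbp4, which codes for a binding protein of insulin-like growth factors (159 and 52.0 CPM, log2 -1.61). With them were the sterol sensor gene Insig1 (60.6 and 21.5 CPM, log2 -1.49), Trf (-1.33), Vstm4 (-1.36), Mrln (-1.27), the splicing factor gene Srsf5 (313 and 138 CPM, log2 -1.18), Ankrd1 (-1.17) and Cirbp. The lists of quiescence (median -0.13, percentile 2.16), heat shock (-0.11), immediate early genes of dissociation (-0.07), matrix (-0.16), interferon response (-0.18) and neutrophil genes (-0.38) lay below 0. The activation and differentiation list lay above it (0.17, percentile 96.4) and ribosomal proteins were at 0.00. Part of this rests on the cycling cells. Without them quiescence was at -0.10 (percentile 11.7), activation and differentiation at 0.09 (percentile 88.9) and immediate early genes at 0.05. Chemokine genes differed in size and direction. Ccl2, which draws monocytes (ENSMUSG00000035385, 11:82035571-82037453, plus strand), was higher at 18.8 and 40.2 CPM (log2 1.09 [0.76, 1.44]), as were Ccl7 (1.60), Ccl11 (1.26) and Csf1 (0.85). Cxcl1, which draws neutrophils, was lower at 584 and 404 CPM (log2 -0.53 [-0.61, -0.46]). Other classes of the library reach 240 CPM of Ccl2 and 1311 CPM of Ccl11. The unnamed Lyve1-led cluster holds Ccl2 at 1084 CPM at ZT4 and 1174 CPM at ZT16, so free RNA can add to these levels. Ccl2 was at 0.31 [-0.06, 0.69] without the cycling cells. The chemokine list had a median of 0.16 (10 genes, percentile 89.8), which turned to -0.16 without the cycling cells and to -0.23 with doublets kept, but was 0.85 for members with at least 100 UMIs. The NF-kB list was at 0.05 (percentile 76.0), the sex-linked list at -0.09 and the list of other cell types' genes at 0.06. The repair macrophage list was at 0.03 and the inflammatory macrophage list at -0.75 (2 genes).

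**Figure D3:**
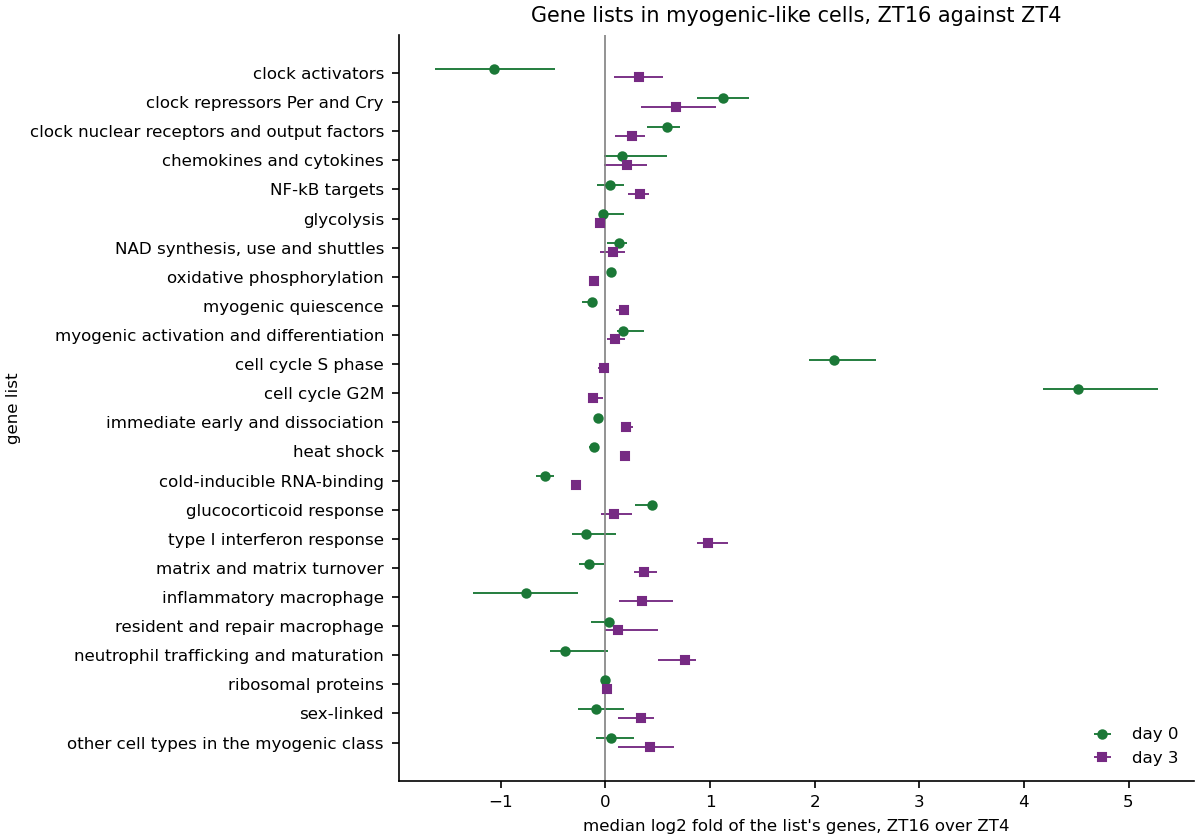
Median log2 fold between ZT16 and ZT4 of each gene list in myogenic-like cells of day 0 and day 3. Bars are 95% limits from 500 Poisson draws.

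On day 3 the question was whether regenerating myogenic-like cells, by then expressing Myog, still differ by collection time. The clock difference was incomplete, with smaller folds than on day 0 in Nr1d1, Per2, Per3 and Cry1. The days were not tested against each other, the Per2 intervals overlap, and the day 3 cells were far deeper. For the repressor list the order of the days is open. Its day 0 value was 0.478 in cells thinned to 1000 UMIs, below the day 3 alternatives (0.585 to 0.988). The thinned value may rest on fewer members, since those under 30 UMIs drop out, so it does not settle the order. Per2 was higher at ZT16 at a low level, 0.963 and 2.64 CPM (log2 1.44 [0.75, 2.19]), Cry2 was at 0.68, Per3 at 0.55 and Cry1 at 0.15, and the repressor list had a median of 0.68 (percentile 99.4). Per1 was at 1.01 but reaches 131 CPM in another class and turned to -0.14 in cells thinned to 1000 UMIs. Nr1d1 was low and hardly different (6.24 and 5.22 CPM, log2 -0.25 [-0.63, 0.11]). Arntl (0.39) and Dbp (0.21) lay slightly above 0, with the activator list at 0.32, the output list at 0.25 (percentile 76.7) and the glucocorticoid list at 0.08. Genes higher at ZT16 by the naming rule included the imprinted genes H19, a long non-coding RNA of embryonic and regenerating muscle (119 and 278 CPM, log2 1.23), and Peg3 (232 and 393 CPM, log2 0.76). They also included Hspa5 (284 and 495 CPM, log2 0.80) and Xbp1 (35.8 and 57.9 CPM, log2 0.70), which serve protein folding in the endoplasmic reticulum, and Gpx3, Errfi1, Myh9, Pmepa1 and Flnc. Lower were Gstp1, which codes for a detoxifying enzyme (81.8 and 40.5 CPM, log2 -1.01), Angptl4 (64.6 and 34.6 CPM, log2 -0.90), Srsf5 (-0.76), Spp1 (467 and 340 CPM, 1857 in another class), Hnrnpdl and Ociad2. So were 2 histone genes whose copies cannot be told apart, Hist1h2ap (-1.43) and Hist1h2ae. Lars2, higher at ZT16 (log2 1.94), moved the same way in all 10 classes compared on day 3. It shares sequence with another gene and is read as a difference between the libraries, as is Wdr89, lower at ZT16 in 10 of 10 classes (log2 -1.35 to -0.88).

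Among lists on day 3, cell cycle genes hardly differed in myogenic-like cells (S phase -0.02, G2M -0.12), nor did glycolysis (-0.06), NAD genes (0.07), oxidative phosphorylation (-0.11) or ribosomal proteins (0.02). Heat shock (0.18, percentile 99.9), immediate early genes (0.19, percentile 99.7), NF-kB targets (0.33, percentile 99.8, -0.05 with free RNA subtracted), matrix (0.37, percentile 99.95), quiescence (0.17) and activation genes (0.10) lay above 0 and cold-inducible genes below it (-0.28). The interferon list was higher at ZT16 (median 0.985, percentile 100, 14 of 15 genes at least 1.5-fold), yet 14 of the 15 genes stood under 10% of their level in another class, as Isg15 did with 24.0 and 69.6 CPM against 1344, and the median turned to -0.47 once free RNA was subtracted. Chemokines had a median of 0.20 (percentile 63.3), -0.36 with free RNA subtracted. Ccl2 was at 8.31 and 6.07 CPM (log2 -0.45) against 535 CPM in another class, and Cxcl1 was at 16.2 and 15.9 CPM. Lists of other cells' genes were also above 0: inflammatory macrophage 0.35, repair macrophage 0.12, neutrophil 0.76 and other cell types 0.43. The inflammatory list turned to -0.35 and the list of other cell types to -0.04 in thinned cells, and the inflammatory list to -0.05 with doublets kept and to -0.007 with free RNA subtracted. The sex-linked list was at 0.35.

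Some genes held the same direction in myogenic-like cells on both days that could be compared. Higher at ZT16 on day 0 and day 3 were Scd2, which codes for a fatty acid desaturase (log2 0.89 and 0.53), Glul, which codes for glutamine synthetase (0.63 and 0.41), Nfic (0.76 and 0.44), the nuclear RNA Neat1 (0.52 and 0.54), and Hsph1 (0.36 and 0.58). So were Lars2 (0.61 and 1.94) and the histone genes Hist1h4d (1.26 and 0.65) and Hist1h1e (1.17 and 0.45). Lower were Srsf5 (-1.18 and -0.76), Cirbp (-1.13 and -0.40), the metallothionein gene Mt1 (-0.41 and -0.32), Actg1 (-0.48 and -0.30), Snhg3 (-0.58 and -0.39), Fcf1 (-0.45 and -0.35), Fam204a (-0.46 and -0.35) and Rraga (-0.40 and -0.29). Over 7745 genes the day 0 and day 3 log2 values were unrelated (Pearson r -0.034, Spearman rho 0.008, genes not being independent replicates). With r at 0.034 from mean per-cell CPM and 0.02 with free RNA subtracted, even its sign is open.

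Next came the question what injury does to the myogenic-like cells, comparing day 3 with day 0 at each collection time. Summed over the class, quiescence genes were lower and differentiation genes higher on day 3. By the day 0 rule, 604 of 697 cells at ZT4 and 416 of 492 at ZT16 also counted as cycling, at greater depth. Which cells differentiated was not looked at cell by cell. The stem cell factor gene Pax7 (ENSMUSG00000028736, 4:139737062-139833528, minus strand) was at 534 CPM on day 0 and 42.9 on day 3 at ZT4 (log2 -3.64), and at 449 and 52.1 at ZT16 (-3.11). Myog, the factor gene of terminal differentiation, was at 4.81 and 845 CPM at ZT4 (log2 7.43) and 23.1 and 823 CPM at ZT16 (5.15). Higher on day 3 by the naming rule were the fusion genes Mymk (ENSMUSG00000009214, 2:27061636-27072179, minus strand; at least 257-fold at ZT4, and 1.67 and 140 CPM at ZT16) and Mymx (at least 343-fold and at least 513-fold). So were the sarcomere genes Tnnt2 (at least 353-fold and at least 529-fold) and Myh3 (at least 107-fold and at least 227-fold). The asparagine synthetase gene Asns (at least 111-fold and at least 145-fold), Tnni1, Ahnak2, Igfbp2 and Trp53i11 followed. Spp1 (at least 809.6-fold and at least 879.6-fold), Lgals3 (2.88 and 691 CPM at ZT4) and Timp1 were also among them. Cells of another class in the day 3 libraries carry Spp1 at 1857 CPM, so free RNA can add to that gene. Lower on day 3 were the natriuretic peptide gene Nppc (ENSMUSG00000026241, 1:86666291-86670571, minus strand; 2146 and 4.92 CPM at ZT4, log2 -8.76, and 1155 and 3.96 at ZT16, -8.18), Ccl19 (-7.88 and -8.35) and Chodl (-7.09 and -6.78). The others were Dpt, Hsd11b1, S1pr3, Rarres2, Bmp4 (431 and 4.74 CPM at ZT4), Hmcn2, Edn3 and Chrdl2. Different clusters held these cells on day 0 (cluster 10) and day 3 (cluster 20), and the class was deeper on day 3. Levels are parts of the class total, so lower values on day 3 need not mean fewer transcripts per cell.

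Clock output genes were far lower in the day 3 cells. Output factors had median log2 values of -3.33 at ZT4 and -3.25 at ZT16, Per and Cry repressors -2.84 and -2.46, and activators -1.58 and -0.25. Single genes included Dbp, an output factor gene (193 to 8.95 CPM at ZT4, log2 -4.43, and -4.06 at ZT16), Nr1d1 (-4.23 and -2.46), Per3 (-3.65 and -4.23), Per2 (-2.20 and -3.36) and Arntl (-1.58 and -0.13). Cry1 went the other way at ZT4 (3.85 and 9.09 CPM, log2 1.21 [0.58, 1.98], but -0.38 in thinned cells) and was lower on day 3 at ZT16 (-0.62). Quiescence genes had medians of -3.47 and -3.21, with Calcr, Spry1 and the Notch target Hes1 (-2.75 and -2.51) among them. Activation and differentiation genes had 3.44 and 3.61 (2.64 at ZT16 with genes near 0 at their bound). At ZT4 that median was 4.27 in thinned cells and 2.97 under the stricter filter, and at ZT16 it was 4.07 and 2.47. G2M genes were at 6.17 and 1.92 (6.13 at ZT4 at the bound) and S phase genes at 3.70 and 1.52, the gap between times coming from the dividing day 0 cells of ZT16. Glycolysis (1.18 and 0.70, with Ldha at 1.57 and 1.21) and oxidative phosphorylation (1.08 and 0.91) were higher on day 3. Lower were glucocorticoid genes (-2.14 and -2.46), matrix genes (-1.72 and -1.38) and immediate early genes (-4.40 and -4.09, Fos from 12834 to 353 CPM at ZT4), which cell isolation also switches on. Chemokines were at 0.25 and 0.54, the latter turning to -0.41 under the stricter filter, -3.11 in thinned cells and -5.33 with free RNA subtracted. NF-kB targets were at -0.33 and -0.27, NAD genes at 0.12 and 0.07, and heat shock at 0.03 and 0.44. Cold-inducible genes were at 0.19 and 0.49, interferon genes at -0.01 and 0.81 (-1.005 at ZT16 with free RNA subtracted), ribosomal proteins at 0.01 and 0.04, and sex-linked genes at -0.70 and -0.56. Macrophage and neutrophil lists (inflammatory 3.31 and 4.17, or 2.89 and 3.28 at the bound, repair 0.96 and 1.36, neutrophil 1.90 and 2.62) were higher on day 3 and the list of other cell types was lower (-2.04 and -2.41). The repair macrophage list turned to -1.87 and -1.40 in thinned cells, to -0.91 and -0.12 with doublets kept and to -3.73 and -10.47 with free RNA subtracted, and the neutrophil list to -2.61 and -1.30 in thinned cells. Medians in thinned cells can rest on fewer list members, so such turns need not be turns of the same genes. Day 1 was not compared with day 0, since 14 and 35 cells fall under the limit of 50.

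**Figure D4:**
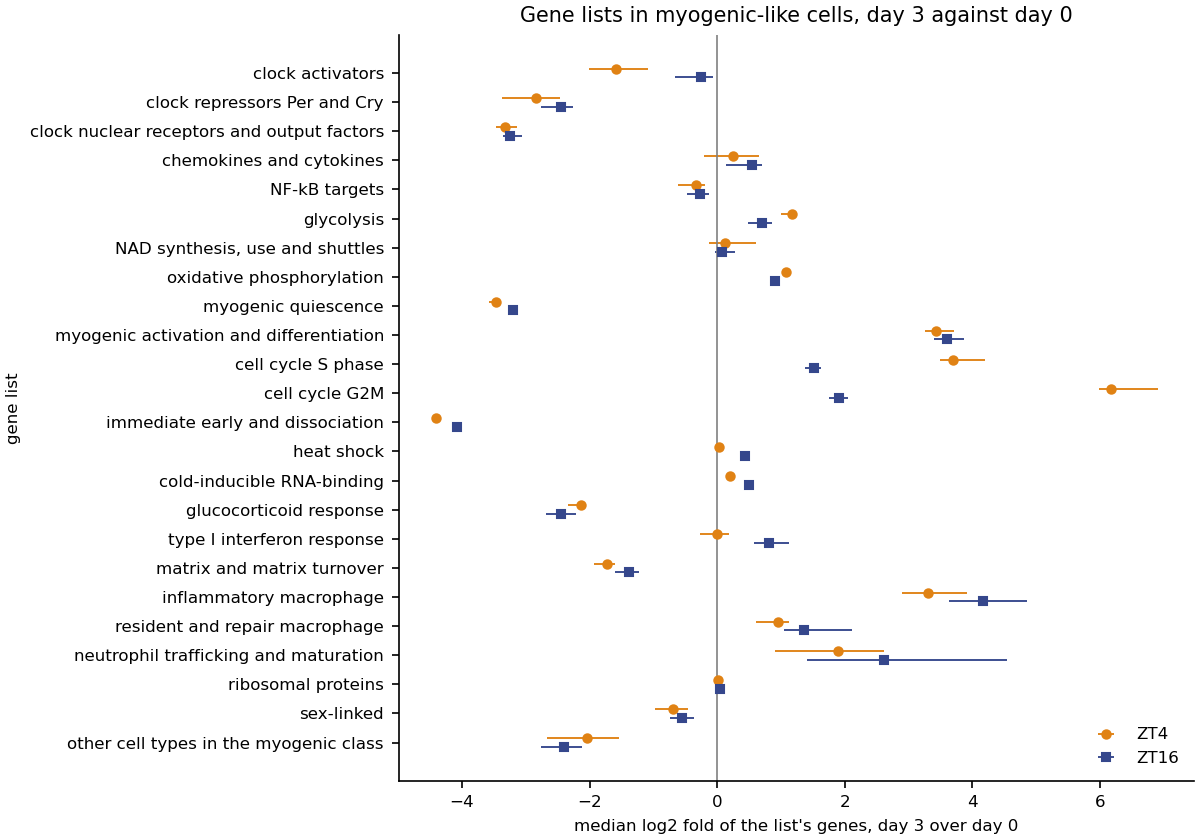
Median log2 fold between day 3 and day 0 of each gene list in myogenic-like cells at ZT4 and ZT16. Bars are 95% limits from 500 Poisson draws.

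The fourth question was whether the clock difference is shared by the other cells of the muscle. On day 0 the repressor list lay above 0 in 8 of 8 classes (0.70 to 2.17) and the output list in 9 of 9 (0.23 to 1.00). Per2 was higher at ZT16 in 5 of 5 classes, Per3 in 7 of 7, Cry1 in 6 of 6 and Dbp in 6 of 8, and Nr1d1 was lower in 8 of 8 and Arntl in 5 of 5 (log2 -5.31 to -1.06). Stromal and vessel cells shared the difference. Per2 in fibro-adipogenic-like cells was at 1.84 and 52.5 CPM (log2 4.82), Dbp there at 43.8 and 230 CPM (2.39), and Nr1d1 in endothelial-like cells at 103 and 10.6 CPM (-3.27). The Lyve1-led cluster (988 and 653 cells), which is unnamed and not among the classes counted, shared it in part. It had Arntl at 42.2 and 3.68 CPM (log2 -3.48) and Per2 at 2.74 and 45.6 CPM (4.02), but Nr1d1 was not lower there (0.31 [-0.01, 0.63]). Glucocorticoid genes were above 0 in 9 of 9 classes on day 0 (0.38 to 1.82), with Tsc22d3 higher in 9 of 9 and Fkbp5 in 7 of 7, and Cirbp was lower in 9 of 9. On day 1, when nearly all cells were newly arrived immune cells, some genes held this order and others did not. The repressor list was above 0 in 4 of 5 classes, Per3 was higher in 3 of 3, Cry1 in 3 of 4, Tsc22d3 in 6 of 7 and Fkbp5 in 4 of 5. The output list was above 0 in 1 of 6 classes, Dbp was higher in 1 of 4 and Per2 in 1 of 2, while Nr1d1 was lower in 3 of 3 and Cirbp in 7 of 7. On day 3 the repressor list was above 0 in 8 of 8 classes (0.30 to 1.02) and the output list in 10 of 10 (0.01 to 2.40). Dbp was higher in 8 of 8 (log2 0.015 to 0.754), Cry1 in 6 of 6 (0.149 to 1.441) and Nr1d1 lower in 4 of 4 (-2.88 to -0.254). Classes of a day share their libraries, so such counts are not replicates. Arntl was higher in 3 and lower in 2 of 5 classes, the activator list was above 0 in 3 of 7, and Tsc22d3 was higher in 7 of 10. In day 3 cells the repressor list stood at 0.84 in endothelial-like, 0.76 in fibro-adipogenic-like, 0.75 in monocyte-macrophage-like and 0.51 in dendritic-like cells.

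**Figure D5:**
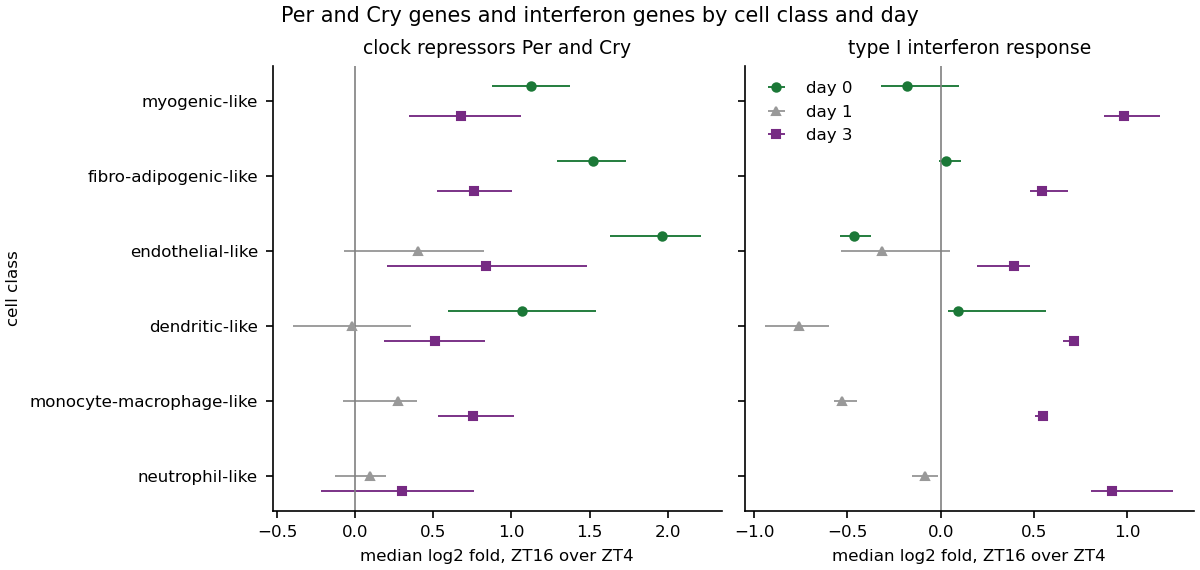
Median log2 fold between ZT16 and ZT4 of the Per and Cry list and the interferon list by class and day. Bars are 95% limits from 500 Poisson draws.

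Endothelial-like and fibro-adipogenic-like cells differed by collection time in further genes named by the rule. Endothelial-like cells had more Lpl, which codes for the lipase that frees fatty acids from blood lipids (ENSMUSG00000015568, 8:68880491-68907448, plus strand), at ZT16 on day 0 (443 and 2711 CPM, log2 2.61), day 1 (138 and 333 CPM, 1.27) and day 3 (248 and 1186 CPM, 2.26). They had less of the tight junction gene Cldn5 on day 0 (1861 and 582 CPM, -1.68) and day 3 (1412 and 731 CPM, -0.95). On day 0 they also had more Bcl2l1 (2.16), Tsc22d3 (1.83), P4ha2 and Adh1, and less Nr1d1, Trp53i11 (-2.08), Cirbp (-1.85) and Nts (-1.54). On day 1 Timp4 (35.6 and 198 CPM, log2 2.46), Sox18, Zfp36 and Tm2d1 were higher and Inhbb (-1.85), Akap12, Ankrd1, Mmp14 and Sh2d5 lower. On day 3 Ccl2 was at 5.65 and 186 CPM (716 in another class). Cyp26b1, Ifi27l2a and Lars2 were higher too, and Il6 (110 and 32.4 CPM, log2 -1.73), Fam181b and Stmn2 were lower. Fibro-adipogenic-like cells of day 0 had more of the monooxygenase genes Fmo2 (33.9 and 288 CPM, log2 3.09) and Fmo1 (2.27) and of Tef (2.28). They had less Hpgd, which codes for the enzyme that breaks down prostaglandins (62.1 and 4.65 CPM, -3.73), the sterol synthesis genes Fdps (-2.14) and Idi1 (-1.95), the sterol sensor gene Insig1 (-1.67), and Arhgap20. On day 3 they had more Ccn2 (1.35), Cxcl10 (99.3 and 239 CPM, 1.27), Dhrs3, Ifit1 and Lars2. They had less Mmp3 (53.6 and 20.6 CPM, -1.38), Bloc1s1, Plat and Ecrg4. Endothelial-like cells of day 0 and of the later days sit in different clusters (cluster 3 and cluster 18), as do fibro-adipogenic-like cells (cluster 6 and cluster 21).

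Immune cells of day 1 differed in inflammatory genes. Monocyte-macrophage-like cells (3886 and 4123 cells) had lower inflammatory macrophage genes at ZT16 (median -0.31, percentile 0.03), NF-kB targets (-0.27), interferon genes (-0.53) and glycolysis (-0.28). Genes of resident and repair macrophages were higher (0.53, percentile 100), with chemokines at -0.11. The mix of clusters in this class differs between the groups, and with clusters weighted alike these medians were -0.43, -0.20, -0.38, -0.27 and 0.31, with chemokines at -0.28. Ifitm6 (226 and 61.1 CPM, log2 -1.89, but -1.05 with clusters weighted alike), Slpi (269 and 82.9 CPM, 1917 in another class), C3 (-1.63) and Mcemp1 (-1.59) were lower. Mthfs, Tppp3, Sft2d1, Hprt and Sdf2l1 (107 and 231 CPM) were higher. Neutrophil-like cells of day 1 (4816 and 4223 cells) had lower NF-kB targets (-0.62) and glycolysis (-0.40). Their mix of clusters differs too, and weighted alike the medians were -0.55 and -0.40, with Srxn1 at -0.93 and Spp1 at -1.07. The oxidative stress genes Srxn1 (71.3 and 22.2 CPM, log2 -1.68) and Gclc (-1.71), Sgms2 (-1.67), Ralgds (-1.60) and Spp1 (1152 and 387 CPM, 2588 in another class) were lower, and Chil3 (25.6 and 105 CPM, 620 in another class), Jaml (91.6 and 201 CPM), Evi2, Ltc4s and Fbxl14 were higher. Dendritic-like cells of day 1 had more of the division genes Stmn1, Pclaf, Tuba1b and Dut and of Mgst3. They had less Cxcl10 (59.4 and 7.77 CPM, log2 -2.92), Ly6a, Lpl, C1qa and Ccl22. Lpl turned to 0.43 there under the stricter cell filter.

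On day 3 interferon genes were higher at ZT16 in all 9 classes measured (0.39 to 0.99). With the estimated free RNA subtracted, the median turned below 0 in myogenic-like cells and stayed at 0.72 in dendritic-like cells. Neutrophil-like cells (284 and 173 cells) had a median of 0.92 (0.62 with clusters weighted alike, as their mix differs between the groups), with Ifit1 (74.0 and 298 CPM), Ifit3 (75.5 and 288 CPM), Cmpk2 and the T cell attractant gene Cxcl10 (87.5 and 290 CPM, 1.72) higher, with Lars2. Spp1 (709 and 144 CPM, 1857 in another class), Mt1, Pdcd1lg2 (log2 -2.03, but -1.05 with clusters weighted alike) and Gpnmb were lower. Monocyte-macrophage-like cells (5098 and 4781 cells) had an interferon median of 0.55, with Oas3 (73.4 and 137 CPM, log2 0.90), the immediate early gene Egr1 (148 and 266 CPM, 0.85), Gda, Ly6a and Lars2 higher. Gpr183, an oxysterol receptor gene of cell migration (135 and 63.4 CPM, -1.09), Pkib and Ifi27 were lower, with chemokines at -0.01 and NF-kB targets at 0.13. Dendritic-like cells of day 3 had more of the T cell attractant gene Ccl22 (32.7 and 96.6 CPM, log2 1.56), Gda, Ccnd2, Gbp2 and Lars2, and less Hist1h2ap, Cirbp and Ifitm1. On day 0 Ccl22 had been lower there at ZT16 (79.3 and 27.2 CPM, -1.54, but 0.39 with clusters weighted alike), with Ccl24, Lpl, Lyz1 and Skint3, while Abcg1, Ccl3 (26.3 and 76.9 CPM, 1.54), Pclaf and Stmn1 were higher. Mucl1, with 3 and 653 UMIs, turned to -5.65 under the stricter filter. Dendritic-like cells of day 0 and the later days again sit in different clusters (cluster 26 and cluster 9).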

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

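The tests of explanations in this part were chosen only after the results were seen, though free RNA subtraction and equal cluster weights had been fixed earlier as alternatives. None of the differences between days given here was tested. A closer look was given to each list median that lay at least 1.2-fold above 0 at ZT16 on 1 day and at least 1.2-fold below 0 on another. For class shares and single clock genes the limit was 1.5-fold on both sides. Of 144 series of a list in a class, 17 met the rule, while 0 of 15 class shares and 0 of 20 clock genes met theirs. These counts are not alike, since each clock gene was looked at in up to 6 classes but counted as 1. Glial-like, tenocyte-like and Lyve1-led shares had a ratio on day 0 only, so they could not meet the rule. Values follow as log2 of ZT16 over ZT4.

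In myogenic-like cells, the clock activators were at -1.063 on day 0 and 0.324 on day 3, the inflammatory macrophage list at -0.754 and 0.354, and the neutrophil list at -0.384 and 0.76. In endothelial-like cells, chemokines and cytokines, whose products call in leukocytes, were at -0.387 on day 0, -0.269 on day 1 and 0.27 on day 3. The interferon list there was at -0.463, -0.314 and 0.394, and the inflammatory macrophage list at -0.605 on day 0 and 1.75 on day 3. In dendritic-like cells, clock activators were at -0.683 on day 1 and 0.527 on day 3, and the interferon list at -0.761 and 0.718. The list of myogenic quiescence genes there was at -0.448 on day 0 and 0.264 on day 1. The list of myogenic activation and differentiation genes was at 0.478, -0.271 and -0.378 over the days, and the G2M list at 0.862, 0.64 and -0.272. The myogenic lists say nothing on rest or activation of dendritic-like cells. In monocyte-macrophage-like cells the G2M list was at 0.282 on day 1 and -0.497 on day 3, and the interferon list at -0.527 and 0.548. In neutrophil-like cells NF-kB targets were at -0.623 on day 1 and 0.313 on day 3, S phase genes at 0.277 and -0.503, the resident and repair macrophage list at 0.766 and -0.639, and ribosomal proteins at 0.33 and -0.276.

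Some of these opposite directions go away with another processing. In dendritic-like cells thinned to 1000 UMIs, myogenic quiescence genes were at -0.367 on day 1 and myogenic activation genes at 0.009 on day 3. With all members of at least 1 UMI, clock activators there were at 0.062 on day 1. S phase genes in neutrophil-like cells of day 3 were at 0.529 in thinned cells. The inflammatory macrophage list in myogenic-like cells of day 3 was at -0.345 in thinned cells, with no such value on day 0 to set beside it. Medians in thinned cells can rest on fewer list members than the main values.

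Interferon genes, which cells switch on in answer to interferon and viral or self nucleic acid, were lower at ZT16 on day 1 and higher on day 3 in 3 of these classes. In myogenic-like cells of day 3 the median was -0.472 once free RNA was subtracted, so there the difference may be RNA from other cells. The same subtraction left dendritic-like cells at 0.716. Monocyte-macrophage-like cells stayed at 0.537 with clusters weighted alike, so another mix of these clusters does not explain them. Cluster 2, whose leading genes include Cxcl10 and Irf7, held 49.1% of them at ZT4 and 51.3% at ZT16 on day 3. Another mix of cell states within a cluster was not tested. A difference between single animals or muscles stays open, with the macrophage value at -0.527 on day 1. A second animal at each time would be needed to tell it from an effect of the hour of injury or collection.

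Lars2, which codes for a mitochondrial leucine tRNA synthetase, was at least 1.5-fold higher at ZT16 on day 3 in 10 of 10 compared classes. Such a shift in all cells may come from how the library was made or read, since Gm42418, which overlaps ribosomal RNA, shifted with it and Wdr89 was lower in 10 of 10 classes. In whole libraries Lars2 was at 169 CPM at ZT4 and 493 CPM at ZT16 on day 3. Its median log2 over the classes was 0.395 on day 0 and -0.051 on day 1. What set the day 3 libraries apart stays open.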

How the results depend on the processing

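Tests named in this part as added were chosen only after the results were seen. The limits of these data are 1 library per group, shares that depend on dissociation and sorting, free RNA in low-level genes, and day 1 groups too small to compare. No paired analysis was possible because each comparison sets 1 library against 1 other and comes from no test. Over all alternatives, 221 of 241 share ratios, 2425 of 2581 list medians, 6427 of 6585 gene folds and 10 of 12 correlations over days kept their sign. The cause of a shift was not tested unless said. The myogenic-like share lay at 0.029 to 0.183 on day 0, with 8 of 8 alternatives above 0, and at -0.354 to -0.132 on day 3, with 8 of 8 below. The Per and Cry list stayed above 0 on day 0 in 15 of 15 (0.478 to 1.237) and on day 3 in 13 of 13 (0.585 to 0.988), and the output list on day 0 in 15 of 15 (0.454 to 0.702). Leiden resolution 2.0, median-of-ratios factors, totals without mitochondrial and ribosomal genes and clusters not divided further turned or moved none of the values listed next. Free RNA subtraction gave no value for endothelial-like cells of day 0, fibro-adipogenic-like cells of day 0 and day 3 and monocyte-macrophage-like cells of day 3, where its estimated share was over 20%, nor for neutrophil-like cells, whose genes serve to measure it. In mural-like cells of day 0 at ZT4 the estimate was 138.553%, so it takes in more than free RNA, and values that rest on it in other classes are rough. The turn of the neutrophil list under subtraction follows from its construction.

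With each library clustered alone, share ratios were 0.877 for dendritic-like cells on day 0, -0.117 and 0.056 for neutrophil-like cells on day 1 and day 3, and -0.132 for myogenic-like cells on day 3. With immune or non-immune denominators they were 0.348 (dendritic, day 0), -0.129 (neutrophil, day 1), -0.133 (myogenic, day 3) and -0.085 (mural, day 1). With doublets kept, the tenocyte share on day 0 was -0.004. In myogenic-like cells chemokines were then at -0.227 on day 0 and -0.162 on day 3, and on day 3 interferon genes were at 0.65, inflammatory macrophage genes at -0.053, Ccl9 at -0.116 and Il1b at -0.392. After injury output factors were at -3.757 (ZT4), activation genes at 3.149 (ZT4) and 2.536 (ZT16), repair macrophage genes at -0.914 (ZT4) and -0.124 (ZT16) and Ccl9 at -0.526 (ZT4).

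Without a cell filter, chemokines were at -0.135 on day 0 and interferon genes at 1.186 on day 3 in myogenic-like cells, and G2M genes at -0.423 in dendritic-like cells of day 1. Under the stricter filter, Mucl1 was at -5.653 (dendritic, day 0) and Lpl at 0.429 (dendritic, day 1), and after injury output factors were at -3.489 (ZT4), activation genes at 2.969 (ZT4) and 2.469 (ZT16) and chemokines at -0.412 (ZT16). Leiden resolution 0.5 put myogenic activation genes in dendritic-like cells of day 1 at 0.593. With clusters weighted alike, Ccl22 in dendritic-like cells was at 0.394 on day 0 and the myogenic activation genes there at 0.006 on day 3. Mean per-cell CPM gave 3.899 for G2M genes in myogenic-like cells of day 0, after injury -2.816 (ZT4) and -2.85 (ZT16) for output factors and 3.943 and 4.02 for activation genes, and a correlation over days of 0.034.

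List members under 30 UMIs after thinning drop out, so thinned list medians can rest on fewer genes than the main values. Thinning to 1000 UMIs gave 0.478 for the Per and Cry list in myogenic-like cells of day 0. On day 3 it gave -0.345 for inflammatory macrophage genes, -0.042 for genes of other cell types, 0.305 for Ccl7, -0.133 for Klf9 and -0.14 for Per1. In dendritic-like cells it gave -0.367 for myogenic quiescence genes on day 1, and 0.009 for myogenic activation genes and -0.03 for Rora on day 3. Nr1d2 in monocyte-macrophage-like cells of day 1 was at 0.052 and S phase genes in neutrophil-like cells of day 3 at 0.529. After injury at ZT4 it gave 4.265 for activation, -1.872 for repair macrophage genes, -2.614 for neutrophil genes and -0.379 for Cry1, and at ZT16 -2.449 for output factors, -3.111 for chemokines, 4.073 for activation, -1.399 for repair macrophage genes, -1.297 for neutrophil genes and -2.372 for Cxcl2.

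Free RNA subtraction in myogenic-like cells of day 3 gave -0.357 for chemokines, -0.052 for NF-kB targets, -0.472 for interferon genes, -0.007 for inflammatory macrophage genes, -7.657 for neutrophil genes and -8.495 for Cxcl10, and a correlation over days of 0.02. After injury at ZT4 it gave -3.729 for repair macrophage genes, -6.709 for neutrophil genes, -4.913 for Ccl9, -0.467 for Cxcl2 and -4.939 for Il1b. At ZT16 it gave -5.334 for chemokines, -1.005 for interferon genes, -10.474 for repair macrophage genes, -9.838 for neutrophil genes, -9.155 for Cxcl10 and 0.404 for Cxcl12. List members with at least 100 UMIs gave 0.851 and -0.03 for chemokines in myogenic-like cells of day 0 and day 3. They gave -0.019 for myogenic quiescence genes in dendritic-like cells of day 1 and 2.66 for activation after injury at ZT16. Members with at least 1 UMI gave -0.134 for chemokines on day 0 and 0.062 for dendritic clock activators on day 1. Leaving out cycling cells, an added test, gave -0.155 for chemokines, 0.244 for G2M genes and -2.723 for Mki67 in myogenic-like cells of day 0, the last pair by construction.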

Other observations

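All tests in this part were chosen only after the results were seen. The cycling myogenic-like cells of uninjured muscle at ZT16 carried genes of activated muscle stem cells beside genes of resting ones. They held Myod1, the factor gene of activated stem cells, at 517 CPM, Pax7 at 143 CPM, Myog at 39.9 CPM and Chodl, which marks the resting cells of day 0, at 326 CPM. In day 0 cells outside the cycling set Myog was also higher at ZT16 (4.85 and 20.7 CPM, log2 2.07). Ccl2 stood at 161 CPM in the cycling cells, above its level in the class as a whole.

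Other classes of day 0 held cycling cells too. They made up 0.418% of fibro-adipogenic-like cells at ZT4 and 1.19% at ZT16 (thinned, 1 of 2928 with 180 left out and 10 of 2363 with 168 left out), 4 of 2171 and 4 of 2566 endothelial-like cells, and 8.98% and 16.6% of dendritic-like cells. Cells of the B cell-like class numbered 123 at ZT4 and 9 at ZT16 on day 0, T cell-like cells 98 and 53, and all immune cells, with the Lyve1-led cluster counted among them, 13.8% and 8.40% of the kept cells. The haemoglobin gene Hbb-bs was at 1129 and 905 CPM in these libraries.

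The dividing cells of day 0 could be a sampling effect, and several sources were checked. Cells of the day 3 libraries read in this library are excluded: Tnnt2, Mymx and Spp1 together had an upper limit of 3.151 CPM in the cycling cells, against 742.569 CPM in all myogenic-like cells of the day 3 library where they were lower. Droplets with a second, dividing dendritic-like, fibro-adipogenic-like or endothelial-like cell do not account for them. Ptprc, Pdgfra and Pecam1 reached at most 0.515% of their level in cycling cells of these types. A second myogenic-like cell, or one of a type without these genes, could not be told this way and stays open. The cycling cells had a median of 16439 UMIs, against 6759.5 in the class. Doublet removal did not take the cycling cells of ZT4, where the share was 0.618% with doublets kept. A difference between animals that does not come from the clock, such as mild damage or age, stays open, as 1.185% of fibro-adipogenic-like cells of the same library also cycled. Counting cycling myogenic cells in 4 or more animals per time, with EdU given before collection, would decide it.

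Small day 1 groups are given as values only. Their chemokine and cytokine genes went both ways, and free RNA was not subtracted. Myogenic-like cells (14 at ZT4 and 35 at ZT16) had Ccl2 at 31.0 and 67.5 CPM and Cxcl3 at 53.8 and 160 CPM, but Csf1 at 267 and 169 CPM. Their Myod1 was at 672 and 901 CPM and their Pax7 at 31.0 and 34.2 CPM. Fibro-adipogenic-like cells (49 and 58) had Ccl2 at 987 and 2537 CPM, Cxcl1 at 1178 and 1939 CPM, Cxcl2 at 99.2 and 416 CPM and Cxcl5 at 1273 and 2345 CPM. Lower at ZT16 there were Cxcl14 (3988 and 2672 CPM), Cxcl9 (89.6 and 1.46 CPM) and Nr1d1 (33.1 and 8.77 CPM). A cluster led by Cxcl5, Timp1 and Tnc (76 and 167 cells, 0.759% and 1.63%) overlaps both groups, since some of its parts are named myogenic-like or fibro-adipogenic-like. It had Ccl2 at 1960 and 4169 CPM, Ccl7 at 1058 and 1459 CPM and Cxcl3 at 19.3 and 132.1 CPM. Its leading gene Cxcl5 was lower at ZT16 (2395 and 1972 CPM), as were Il1b (113 and 37.9 CPM) and Cxcl9 (34.7 and 1.17 CPM). Myod1 was at 186 and 237 CPM and Dbp at 6.83 and 29.5 CPM.

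The Lyve1-led cluster of day 0 held a wide clock difference with Cry1 at 1.37 and 18.6 CPM (log2 3.69), Dbp at 36.5 and 152 CPM (2.06), Tef at 2.10 and Fkbp5 at 4.41 and 41.9 CPM (3.23), but Nr1d1 at 0.31. Its Il1b was at 123 and 256 CPM (1.05), Cxcl2 at 1297 and 1773 CPM and Ccl2 at 1084 and 1174 CPM.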
